A study of Arabidopsis thaliana with 4 samples.

How the data were processed

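RNA from whole 2-week-old Arabidopsis thaliana seedlings was measured on Affymetrix ATH1 arrays, which read each transcript with a set of short oligonucleotide probes (a probe set). Per the labels, 6 µg of total RNA per sample was turned into biotin-labelled target. There were 4 arrays, 1 per genotype: the Nossen wild type (NO), the duf761-1 mutant in the Nossen background, the Columbia wild type (Col-0), and the OE6 line, a DUF761-1 overexpressor in Columbia. The genotypes were taken from the labels. No genotype had a replicate array.

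The deposited values are linear signal intensities per probe set, made by the authors with MAS5, per the submitters' processing notes, with the version not given in the sources used here. From the values themselves, each deposited array has a mean intensity of 500 after trimming 2% of the probe sets at each end, so the arrays were scaled to a common mean. The table holds no detection calls and no missing values. It has 22810 probe sets, of which 64 are array controls. MAS5 summarises each array separately and is noisy at low signal, so small values carry little information about ratios, and a common mean hides any difference in total mRNA.

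The starting point here was that intensity table. A floor was set at the 40th percentile of the non-control probe sets pooled over the 4 arrays, a signal of 102. Lower values were raised to it and log2 was taken. A ratio with 1 side at the floor is a bound and is written as at least that far apart. A gene at or below the floor on both arrays has no ratio and counts as 0. Of the probe sets, 13513 carry 1 gene name in the annotation table used here, 503 carry several genes and were not named, and 8730 non-control probe sets are unnamed here, which says nothing about whether they have a gene. Names were updated through a reference gene table of assembly TAIR10.1, where 13285 of 13355 genes were found. The files name no genome build, so the table served for names and gene order and no coordinates are given. A gene with several probe sets was represented by the one with the highest mean log2 signal. Of the 13355 genes, 7993 were above the floor on at least 1 array, and 1535 have a symbol other than a locus code.

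The comparisons were duf761-1 over NO, OE6 over Col-0 and, for the backgrounds, Col-0 over NO. With 1 array per genotype there is no test, no p-value and no standard error, and the number of arrays limits the precision of each value. Genes were counted by size alone, at 2-fold or more. As a yardstick of measurement noise within arrays, the log2 ratios of 2 probe sets of the same gene were compared over 60 genes above the floor on all arrays. The SD per probe set was 0.28 for duf761-1 over NO, 0.24 for OE6 over Col-0 and 0.42 for Col-0 over NO. This yardstick leaves out differences between plants, cultures and labelling reactions.

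Before the data were examined, 35 gene lists were fixed, holding 600 members. Of these members 89 had a named probe set and 72 were above the floor, so 13 lists had the 3 measured members needed for a median and 9 lists had none. A list's median log2 ratio was placed among 10000 random lists of the same size, drawn with the same make-up over 20 bins of mean expression. This describes these arrays and is not a test of the genotype. A further 25 lists (23 gene families by symbol, the plastid-encoded genes and the annotated pseudogenes) were fixed after the annotation was seen and before any ratio was computed. Another 3 lists were written after the leading genes had been seen and before their own members' values were seen. Lists that need gene descriptions, such as cytosolic ribosomal proteins and histones, were not used here.

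Named genes followed a rule fixed before the data were examined. For duf761-1 over NO and for OE6 over Col-0 these were the 10 highest and 10 lowest log2 ratios among genes with a symbol, with 5 and 5 for Col-0 over NO. From each fixed list outside the central 95% of random lists came the 3 members furthest in the median's direction, and from the other lists up to 2 members with the largest ratios. Up to 5 genes per direction pattern were named from those past the threshold in both comparisons. Genes outside this rule are marked as chosen after their values were seen.

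Alternatives planned before the data were examined were median scaling, quantile normalization, loess within each pair of arrays (span 0.4), floors at the 25th and 60th percentiles, no floor, a pseudocount equal to the floor in its place, a 3-fold threshold, the mean of a gene's probe sets, and leaving out probe sets whose suffix marks possible cross-hybridisation. Scaling on 18 hybridisation spike-in probe sets, counting all non-control probe sets and leaving out plastid-encoded genes were chosen after seeing the data. The 2-fold rule and the list medians were tested on simulated arrays built from the NO or Col-0 values and the noise yardstick, run on 13355 genes. Changes were placed only in genes with a wild-type signal more than 2-fold above the floor, so recovery nearer the floor was not tested. For duf761-1 over NO, the 2-fold rule recovered 98% of genes changed 3-fold, 46% of those changed 2-fold and 2% of those changed 1.5-fold, with 8 unchanged genes past it. For OE6 over Col-0 the shares were 98%, 52% and 0%, with 0 unchanged genes past it. In each comparison, 40 of 40 simulated lists of 8 genes, all shifted by 0.5, left the central range. Of 40 unshifted lists, 1 did. Smaller lists, and lists whose members go in different directions, were not simulated. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.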

Results

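Transcript levels were measured in whole 2-week-old seedlings of 4 Arabidopsis genotypes, grown on medium with 2% sucrose at 22 °C in 16 h of light at 100 µmol per m2 per s and 8 h of dark. The mutant duf761-1 was set against NO, the Nossen wild type, and the overexpressor OE6 against Col-0, the Columbia wild type. DUF761-1 is a protein named for a domain of unknown function. Each genotype was measured on 1 array, so no difference below has a replicate check, and values are compared by size only. The share of non-control probe sets above the floor was 58.9% on the NO array, 58.3% on duf761-1, 61.6% on Col-0 and 61.2% on OE6. The ratio of the 3′ to the 5′ control probe set, a sign of RNA integrity, was 0.846, 0.754, 0.887 and 0.770 for GAPDH on the same 4 arrays, and 1.08, 1.099, 1.16 and 1.27 for ubiquitin. For actin it was 0.279, 0.267, 1.61 and 2.06, which separates the Nossen from the Columbia arrays.

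The labels give no locus for the targeted gene and no table used here names DUF761-1, so its level could not be read by name to check the genotypes. By values alone, 5 of 22746 non-control probe sets were at least 4-fold higher on the OE6 array than on Col-0. The furthest was that of AT4G16790, chosen after its values were seen. Its signal was 5171 on OE6, 91.1 on Col-0, 118 on NO and 24.3 on duf761-1, which is at least 50.6-fold higher on OE6 than on Col-0. Of all 22746, 1 probe set was at least 2-fold higher on OE6 than on Col-0 and at least 2-fold lower on duf761-1 than on NO. It has no gene name here, and its signal was 991 on NO, 487 on duf761-1, 246 on Col-0 and 506 on OE6. This count used floored values. A probe set near the floor of 102 on NO, such as that of AT4G16790, could therefore not be called 2-fold lower on duf761-1. No locus was assigned to DUF761-1 from these values.

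The comparison of duf761-1 with NO asks what differs in the duf761-1 mutant. Plastid-encoded transcripts stood out: of 67 measured, 23 were at least 2-fold higher on the duf761-1 array, 1 was at least 2-fold lower, and their median log2 ratio was 0.68, where the central 95% of random lists spanned -0.07 to 0.03. Among the furthest were rpoA, which encodes the alpha subunit of the plastid RNA polymerase, at a log2 ratio of 2.94 (7.69-fold), and the ribosomal protein genes rps3 at 2.68, rpl36 at 2.30, rpl22 at 2.11, rpl16 at 1.89 and rps19 at 1.69, with rpl14 at least 1.58 higher, though at 0.09 with a floor at the 60th percentile. These 7 genes lie in one block of the plastid genome. The NADH dehydrogenase-like complex genes ndhH (2.29, at lowest 1.44 over the settings run) and ndhE (1.56) and the fatty acid synthesis gene accD (1.78) were also among the 10 highest genes with a symbol. The 1 gene at least 2-fold lower was psbA, which encodes the D1 protein of photosystem II, with a log2 ratio of -1.52 and signals of 5356 on NO and 1872 on duf761-1.

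Among plastid-encoded genes, those for ribosome, polymerase and maturase had a median log2 ratio of 1.31 (19 genes, 13 of them at least 2-fold higher), and those for photosynthesis complexes one of 0.46 (42 genes, 7 higher and 1 lower). This division was made after the values were seen. Which array stood apart differed between these genes. For the 7 genes of the block the median deviation from the mean of the 4 arrays was -2.32 on NO, -0.01 on duf761-1, 1.01 on Col-0 and 1.35 on OE6. For the photosynthesis complexes it was -0.21 on NO, 0.21 on duf761-1, -0.11 on Col-0 and 0.04 on OE6. The signals of atpI and ycf3, chosen after their values were seen, were highest on duf761-1, with atpI at 335 on NO, 746 on duf761-1, 325 on Col-0 and 295 on OE6, and ycf3 at 353, 937, 326 and 576. Nucleus-encoded photosynthesis genes did not move with them: 0 of 8 measured members were 2-fold apart and their median was -0.04. LHCB4.1, a light-harvesting protein, had a log2 ratio of -0.06 and SBPASE, a Calvin cycle enzyme, one of -0.08.

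**Figure D1:**
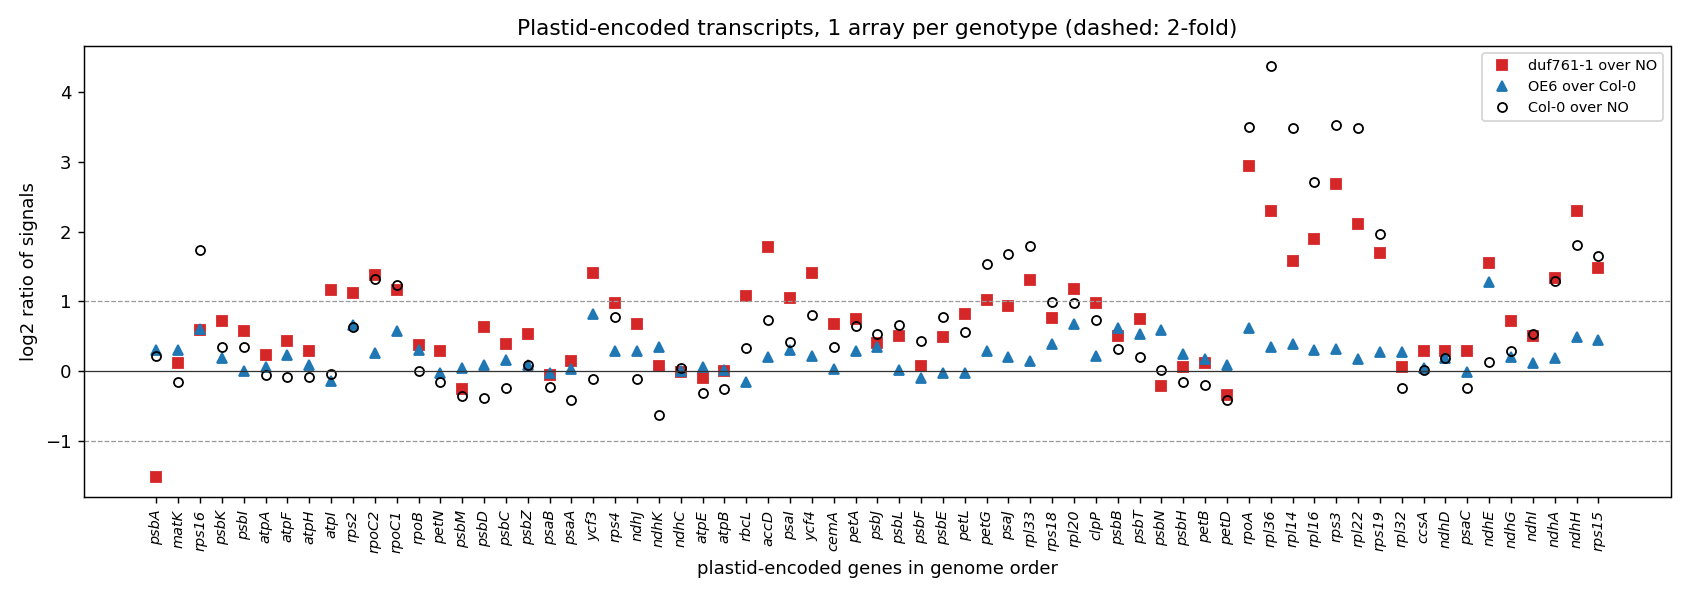
Log2 ratios of signals (vertical axis) for the 67 measured plastid-encoded genes in genome order (horizontal axis), for duf761-1 over NO (squares), OE6 over Col-0 (triangles) and Col-0 over NO (open circles), with 1 array per genotype and dashed lines at 2-fold. The genes from rpoA to rps19 are all above the upper dashed line in both ratios that have NO as denominator, as are some other genes such as ndhH, and psbA (-1.52) is the 1 point below the lower dashed line.

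Outside the plastid genome, the medians of the cell wall and auxin lists were lower on the duf761-1 array, with 1 of 7 and 1 of 4 measured members at the floor on both arrays. In the list of cell wall loosening and growth, 2 of 7 measured members were at least 2-fold lower, 0 were higher, and the median log2 ratio was -0.40, below the central 95% of random lists (-0.18 to 0.20). XTH19 and XTH18, which encode enzymes that cut and rejoin xyloglucan, had ratios of -1.24 and -1.02, and the expansin gene EXPA8 had one of -0.70. XTH16 went the other way at 0.45. XTH18 and XTH19 are close paralogs whose probes may share signal, so their values are uncertain as separate measurements. XTH18 was within 2-fold under quantile normalization, spike-in scaling, the floor at the 60th percentile and the pseudocount, and GH3.3 under the last 2. In the auxin response list, 1 of 4 measured members was at least 2-fold lower and the median was -0.43 (random lists -0.21 to 0.23), with GH3.3, an auxin-conjugating enzyme, at -1.20, the homeobox gene HAT2 at -0.51 and WES1, also a GH3 enzyme, at -0.36. The NO array carried the highest signal of the 4 arrays for XTH19 (2354 on NO, 997 on duf761-1, 659 on Col-0 and 504 on OE6), as it did for XTH18, EXPA8, GH3.3, WES1 and HAT2. For the cell wall list the median deviation from the mean of the 4 arrays was 0.70 on NO, 0.01 on duf761-1, -0.35 on Col-0 and -0.09 on OE6. For the auxin list it was 0.64, -0.04, -0.34 and -0.25. A high NO array would also give these ratios, and with 1 array each this cannot be told apart from an effect of the genotype. EXPA18, a root hair expansin fixed among the root tissue markers, had a ratio of -0.74, while EXPA7, of the same list, was at least 0.50 higher, the root marker PYK10 had one of -0.04 and the root list's median of -0.04 was at percentile 37.4 of random lists.

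**Figure D2:**
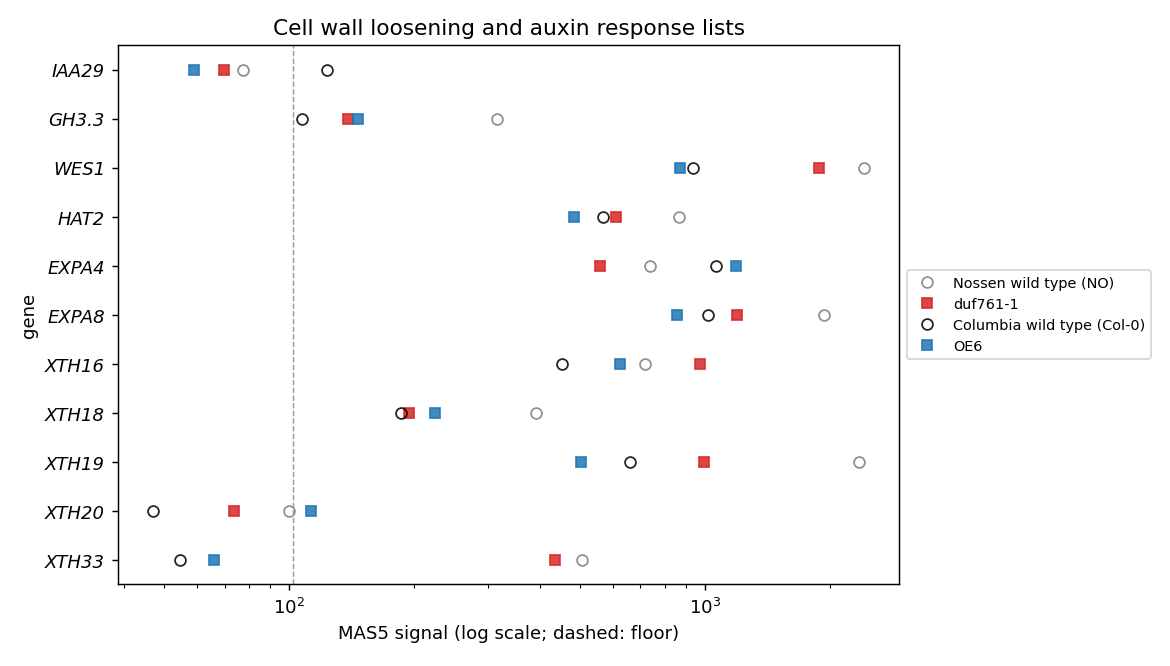
MAS5 signal on a log scale (horizontal axis) for the measured members of the auxin response and cell wall loosening lists (vertical axis), with 1 point per array for the 4 genotypes and a dashed line at the floor of 102. The open grey circle of NO is furthest right for XTH19 (2354), XTH18, EXPA8, GH3.3, WES1, HAT2 and XTH33.

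The oxidative stress and detoxification list was higher on the duf761-1 array, with a median log2 ratio of 0.45 (random lists -0.24 to 0.25), although 0 of its 5 measured members reached 2-fold and 2 were at the floor on both arrays. Its furthest members were the glutathione transferase gene GSTU25 (0.57) and the glucosyltransferase genes UGT73B4 (0.48) and UGT73B5 (0.45). The last 2 are of one subfamily, so their values are uncertain as separate measurements. The wider families were inside their random ranges. Tau-class glutathione S-transferases had a median of 0.05 (9 genes, random lists -0.17 to 0.18). UDP-glycosyltransferases had one of -0.06 (32 genes, random lists -0.09 to 0.09). Other genes with a symbol among the 10 lowest were BGLU19, a beta-glucosidase (-0.94 or lower), the asparaginase gene ASPGA1 (-0.82), the cytochrome P450 gene CYP84A4 (-0.80), the subtilase gene ATSBT5.2 (-0.77) and BRH1, a brassinosteroid-responsive RING finger gene (-0.77). The last 4 did not reach 2-fold, and BGLU19 was at the floor on duf761-1, so its bound leaves this open. Among genes without a symbol, AT5G03090, 5.65-fold higher, and AT3G02860, 3.06-fold higher, were the highest, chosen after their values were seen.

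In all, 53 genes were at least 2-fold higher and 18 at least 2-fold lower on the duf761-1 array than on NO, 0.888% of the 7993 genes above the floor. Without plastid-encoded genes the numbers were 30 and 17. The 10 highest genes with a symbol were all plastid-encoded, so they include none of these 30. Among the 30 were NET1B (1.47) and NET1D (at least 1.35 higher), chosen after their values were seen. With plastid-encoded genes included, the share of higher genes was 74.6%, and 85.5% when arrays were scaled on the spike-ins (59 higher and 10 lower). Of the 13 fixed lists that could be placed, 3 lay outside the central 95%, where 0.65 would by chance if list members varied independently. Aliphatic glucosinolate synthesis (median -0.23) and cell division (-0.17) were inside it. Cold response, flavonoid synthesis and leaf senescence were placed inside it too, but 2 of 4, 2 of 4 and 2 of 3 measured members were at the floor on both arrays and counted as 0, so their medians decide nothing. Members with a ratio were LTI30 (0.62) and COR47 (0.34) for cold response, CHIL (-0.63) for flavonoid synthesis and the transcription factor gene WRKY6 (0.73) for leaf senescence. Both counts move by over 1.5 times with the floor, from 26 higher and 4 lower at the 60th percentile to 120 and 149 at the 25th.

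The comparison of OE6 with Col-0 asks what differs when DUF761-1 is overexpressed. Among genes with a symbol, AMY1, a secreted alpha-amylase, was 5.05-fold higher on the OE6 array (log2 ratio 2.34), SAG29, a sugar transporter of the SWEET family, was 3.69-fold higher (1.88), and cwINV6, a cell wall invertase homologue, was at least 1.51 higher on the log2 scale. Over the settings run, the log2 ratio of AMY1 ranged from 1.11 to 2.47. The expansin-like gene EXLA1 (1.52) and the pectin methylesterase gene ATPMEPCRB (at least 1.44) were also among the 10 highest. The rest of the 10 highest were GSTU25 (1.38), the plastid gene ndhE (1.28), the calmodulin-like gene CML23 (1.27), the defensin gene PDF2.5 (1.23) and the subtilase gene SBT4.12 (1.22). The leaf senescence list also holds SAG29, and its median was -0.05. The 1 fixed list on sugar, of starvation genes, had 1 measured member, MCCA (-0.21). AT4G22470 (2.41) and AT1G52060 (2.07), chosen after their values were seen, were the other named genes at least 4-fold higher besides AMY1 and AT4G16790.

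On the lower side, QQS, a gene known for its effect on starch content, had a log2 ratio of -2.46 or lower on the OE6 array, with a signal of 562 on Col-0. OCT1, an organic cation transporter gene, had a ratio of -1.94 (887 on Col-0 and 231 on OE6). The glutamine amidotransferase gene GAT1_2.1 (-1.17), the linker histone gene HIS1-3 (-1.096) and the protein kinase gene WAG2 (-1.05) were past 2-fold. Of the other 5 of the 10 lowest, MGL, a methionine gamma-lyase gene (-0.98), ATMAP65-6 (-0.91), IAGLU, an auxin glucosyltransferase gene (-0.91), and EXLB1 (-0.83) did not reach it, and SWEET10 (-0.90 or lower) was at the floor on OE6, so its bound leaves this open. Of the genes past 2-fold, GAT1_2.1, CML23, WAG2, cwINV6 and PDF2.5 were within it with a floor at the 60th percentile and with the pseudocount, QQS, EXLA1 and ATPMEPCRB with that floor, and HIS1-3 with the pseudocount. GAT1_2.1 was also within it with the mean of its probe sets, at -0.59.

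**Figure D3:**
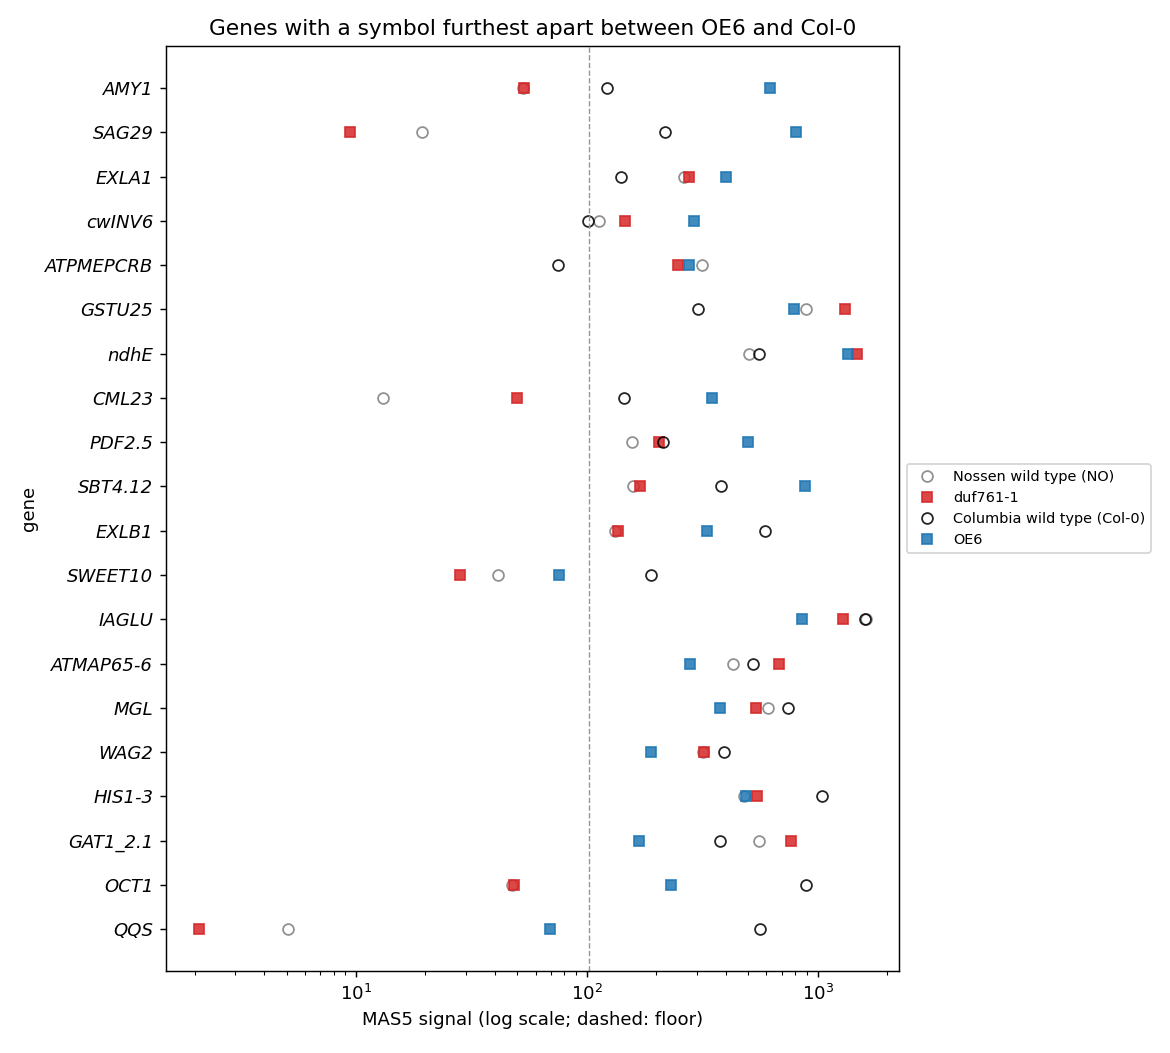
MAS5 signal on a log scale (horizontal axis) for the 10 highest and 10 lowest genes with a symbol in OE6 over Col-0 (vertical axis), with 1 point per array for the 4 genotypes and a dashed line at the floor of 102. For AMY1 (620 on OE6 against 123 on Col-0) and SAG29 (806 against 219) the OE6 point is furthest right, while ATPMEPCRB on OE6 (278) lies among the levels of NO (314) and duf761-1 (247).

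In all, 38 genes were at least 2-fold higher and 39 at least 2-fold lower on the OE6 array than on Col-0, 0.963% of the 7993 genes above the floor. The share of higher genes was 49.4%, and 35.6% with spike-in scaling (31 higher and 56 lower). None of the 13 fixed lists lay outside the central 95% of random lists in the main setting, where 0.65 would by chance if list members varied independently. The nearest was oxidative stress and detoxification, at percentile 96.5 with a median of 0.23, where GSTU25 was 1 of 5 members at least 2-fold higher. The auxin response list had a median of -0.17 with GH3.3 at 0.45, the cell wall list one of 0.14 with XTH16 at 0.47 and XTH19 at -0.39, the flavonoid list one of 0.17, and nucleus-encoded photosynthesis one of -0.01. Plastid-encoded genes had a median of 0.21 (random lists -0.02 to 0.11), with 1 of 67 at least 2-fold higher. Mitochondrion-encoded genes had one of -0.24 (random lists -0.21 to 0.13), with 1 of 10 at least 2-fold lower, and were inside the central range with spike-in scaling (percentile 2.54). Their median deviation from the mean of the 4 arrays was furthest on Col-0, at 0.38. The cell wall list passed the central range at a floor of the 25th percentile and without a floor, with a median of 0.27 in both.

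Set against each other, the mutant and overexpressor ratios, which share no array, had little relation across genes. Pearson's r was 0.05 and Spearman's rho 0.05 over 7993 genes, which are not independent replicates, and r was 0.03 without plastid genes. The SD of the log2 ratios over these genes was 0.31 in both comparisons, not far above the noise yardsticks of 0.28 and 0.24. A small r is therefore likely either way, and it does not tell whether mutant and overexpressor differ in opposite directions. Genes 2-fold apart in both comparisons numbered 1 in opposite directions, where independent lists drawn from all 13355 genes would share 0.206, and 2 in the same direction, where they would share 0.203. Genes never above the floor cannot be 2-fold apart, so these expected numbers are too low for the 7993 genes above it. The gene in opposite directions was AT1G64360, at least 1.36 higher on duf761-1 and with a ratio of -1.17 on OE6. In the same direction were ndhE, higher on both (1.56 and 1.28), and AT5G19890, lower on both (-1.23 and -1.25). With a floor at the 60th percentile AT1G64360 had a ratio of 0.00 in both comparisons and AT5G19890 one of -0.01 on OE6. With the pseudocount AT1G64360 was within 2-fold on OE6 (-0.71), as was AT5G19890 on both (-0.99 and -0.81). With so few genes, the overlap allows no statement on direction.

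The wild types were compared because the mutant and the overexpressor are in different backgrounds. Col-0 and NO differed far more than either line from its wild type, with 722 genes at least 2-fold higher on Col-0 and 407 lower, 14.1% of the genes above the floor. Among genes with a symbol, ECS1 was highest (log2 ratio 6.44, with 23031 on Col-0 and 264 on NO), followed by CCL (5.08), rpl36 (4.37), the clock gene GI, short for GIGANTEA, at least 4.04 higher, and the pyruvate decarboxylase gene PDC2 (3.96). The sugar transporter gene SWEET2 was lowest of the genes with a symbol (-4.62), followed by AOP3, a glucosinolate side chain enzyme gene (-3.43 or lower), HYH, a transcription factor gene of light signalling (-2.96 or lower), AFR, a gene of phytochrome signalling (-2.76), and XTH33 (-2.31 or lower). The cold response list was higher on Col-0, with a median of 1.36 and 3 of 4 members past 2-fold, COR15B at least 2.67 higher, LTI30 at 1.55 and COR47 at 1.16.

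Cell wall loosening (median -0.93, 3 of 7 members lower), auxin response (-0.98, 2 of 4 lower) and flavonoid synthesis (-0.68, 2 of 4 lower and 1 higher) were lower on Col-0. Auxin response was inside the central range with floors at the 25th (-0.16) and 60th percentiles (-0.60). Flavonoid synthesis was inside it with the floor at the 25th percentile (-0.26), without a floor (-0.32) and with the pseudocount (-0.38). UGT78D2, a flavonoid glucosyltransferase gene, had a ratio of -1.36, while its relative UGT78D1 was at least 1.94 higher. NO is the denominator here and in duf761-1 over NO, so the cell wall and auxin values in the 2 comparisons are not independent. ATH1 probes were designed on the Columbia sequence, so a sequence difference in Nossen can lower a signal. The control probe set for the 3′ part of actin read 1462 on NO and 1143 on duf761-1 against 9643 on Col-0 and 10189 on OE6, while the one for the 5′ part read 5232, 4278, 5978 and 4954. The share of higher genes was 64.0%, 49.5% with median scaling (548 higher and 559 lower) and 89.2% with spike-in scaling (1476 and 179), where the median log2 ratio of the genes above the floor was 0.41 in place of 0.04.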

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

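In this part, the scaling test and the test of plastid origin were chosen after the result was seen, as were the median over all plastid genes, the test on poorly matching Nossen transcripts and its scalings. The spike-in scaling was an added alternative. The test on mitochondrial genes, the one on dawn-phased genes and the one on neighbouring genes were written before their results were seen, but the mitochondrial test was narrowed to genes above the floor on either array after a first run over 10 genes gave a median of 0.00.

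Probe sets without a gene name here lie outside the gene-level comparisons, and some stood above or below their wild type. On the duf761-1 array 23 of 8730 were at least 2-fold higher than on NO, with 252325_at furthest at a log2 ratio of 2.22 (26503 against 5698). On the OE6 array 37 were at least 2-fold higher than on Col-0, with 266292_at furthest at 2.15 (583 against 131). On the lower side, 14 were at least 2-fold lower on duf761-1, with 250152_at furthest (-1.78), and 33 on OE6, with 264729_at furthest (-2.52).

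Plastid-encoded transcripts were higher on the duf761-1 array than on NO. More organelle RNA of every kind in the labelled sample is argued against by mitochondrion-encoded genes, whose median log2 ratio was -0.047 over 8 genes, against a plastid median of 0.68. Scaling on the spike-ins left the plastid median at 0.74 but shifts all genes alike and tests nothing here, and for the same reason scaling of the 2 arrays by 1 factor each would not leave nucleus-encoded photosynthesis genes at -0.04. It stays open whether duf761-1 plants carry plastids that match the probes as Col-0 plastids do: plastid genes at least 2-fold higher on Col-0 than on NO had a median log2 Col-0 over duf761-1 of 0.54 over 16 genes, a value raised by picking them on the Col-0 array, while over all 67 plastid genes it was -0.22 (22 above 0). An effect of the genotype on plastid transcripts and a deviation of the single NO array also stay open. On NO the genes from rpoA to rps19 stood apart (-2.32), a value favoured by their place among the highest genes for duf761-1 over NO. Photosynthesis genes stood no further apart on NO (-0.21) than on duf761-1 (0.21). With 1 array each these explanations cannot be told apart.

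GI and CCL were far higher on the Col-0 array than on NO. If the pairs of arrays had been harvested at different times of day, genes that peak at dawn should have lain below the central range of random lists. Their median was -0.47, inside the range of -0.76 to 1.13. With 3 genes its spread of 0.64 is wider than its distance from the bound, so this test cannot decide and harvest time stays open. Genes that peak in the afternoon or evening, a list for which no outcome had been stated, had a median of 2.69, far above random lists (-0.71 to 1.12), with 3 of 3 measured genes at least 2-fold higher on Col-0, and without a stated outcome this decides nothing. Poor matching of Nossen transcripts to the probes predicts that nearly all genes 8-fold apart are higher on Col-0: 74.5% of 55 were (41 higher, 14 lower), short of the 90% it needs and just under the 75% set as the bound against it, by less than the counting spread of 5.87, and the share ran from 69.1% with median scaling to 87.5% with spike-in scaling, so this stays open, as does the untested difference between the cultivars themselves.

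Genes at least 2-fold apart on the duf761-1 and NO arrays would lie together if there were a chromosome segment of another origin in the duf761-1 plants. With plastid genes left out, 1 adjacent pair was found among 47 such genes, where the median of 10000 shuffles was 0 and their central 95% reached 2, so this test neither shows nor excludes such a segment.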

How the results depend on the processing

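Spike-in scaling, counting all probe sets and leaving out plastid genes were chosen after seeing the data. No paired analysis was possible because each genotype has 1 array, and leaving out a replicate is not possible for the same reason. Signal near the floor limits the counts, which move with the floor chosen. Numbers below are higher, then lower, at 2-fold or more. At a floor of the 25th percentile they were 120 and 149 for duf761-1 over NO and 99 and 127 for OE6 over Col-0, with 1087 higher for Col-0 over NO, and 9 genes in opposite and 4 in the same direction in both lines. At the 60th percentile they were 26 and 4, 13 and 12, and 368 and 248, with 0 opposite and 1 the same, and r across genes was 0.0837. Without a floor they were 1101 and 1772, 1016 and 1358, and 2317 and 1690, with 554 opposite and 682 the same. With the pseudocount they were 28 and 3, and 19 and 11, with 270 lower on Col-0 than NO, 0 opposite and 1 the same. At 3-fold they were 10 and 0, 6 and 5, and 247 and 127, with 0 in either overlap, by construction fewer. Spike-in scaling gave 10 lower for duf761-1, 1476 and 179 for Col-0 over NO, and 3 opposite. All probe sets, a larger number by construction, gave 33 lower for duf761-1, 77 and 74 for OE6, 1353 and 901 for Col-0 over NO, and 2 opposite. Leaving out plastid-encoded genes gave 30 higher for duf761-1. For the other differences the cause was not tested.

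The number of fixed lists outside the central range for OE6 over Col-0 was 1 at the floor of the 25th percentile and 1 without a floor, the cell wall list both times, against 0 in the main setting. Other lists inside the range in the main setting left it under an alternative: cold response for duf761-1 over NO at the floor of the 60th percentile (0.34), and for Col-0 over NO early elicitor, wound and touch response (1.35) and leaf senescence (1.38) at the floor of the 25th. For duf761-1 over NO, the auxin and cell wall lists were outside it under all 10 alternatives run and the oxidative stress list under all 9 that left it 3 members, with medians from -0.43 to -0.30, from -0.44 to -0.34 and from 0.28 to 0.51. For Col-0 over NO, cold response and cell wall loosening were outside under all 10, auxin response under 8 and flavonoid synthesis under 7. No list median outside the central range and no named gene past 2-fold changed sign under the alternatives run. Of the values of named genes under alternatives, 2776 moved by less than the noise yardstick and 251 by more. Of list medians, 369 moved by less than the distance from the middle to the edge of the random range and 6 by more, all 6 for Col-0 over NO.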

Other observations

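The phosphate test in this part was written before its result was seen. The genes that prompted it, the second phosphate list and the gene families' scaling checks were chosen after ratios of other genes had been seen.

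Among gene families grouped by symbol, which were fixed before any ratio was computed, the expansins had a median log2 ratio of -0.35 on duf761-1 over NO (10 genes, 0 of them 2-fold apart, random lists -0.17 to 0.19) and the xyloglucan endotransglucosylase/hydrolases one of -0.32 (8 genes, 2 lower). The latter were also lower on Col-0 than on NO (-1.07, 5 of 8 lower), a comparison that shares the NO array. Both families share members with the fixed cell wall list, such as EXPA8, XTH18 and XTH19. The 2 lower genes are XTH18 and XTH19 again, so these medians are not separate support for that list. Serine carboxypeptidase-like genes had a median of -0.16 on duf761-1 over NO. Autophagy genes had a median of -0.18 on OE6 over Col-0 (11 genes), which was inside the central range with median scaling, quantile normalization and loess. Their median was 0.56 on Col-0 over NO (1 of 11 at least 2-fold higher), a comparison that shares the Col-0 array, where their median deviation from the mean of the 4 arrays was 0.30. Of 25 such lists, 4 lay outside the central 95% for duf761-1 over NO, 2 for OE6 over Col-0 and 3 for Col-0 over NO. By chance 1.25 would, if list members varied independently. The counts include the plastid-encoded genes each time.

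OCT1, AT5G20790 and AT1G08310 were lower on the OE6 array than on Col-0, with log2 ratios of -1.94, -1.74 and -1.80. The last 2 were chosen after their values were seen. A weaker phosphate-starvation response in the OE6 seedlings is a candidate explanation: a second list of phosphate-starvation genes had a median of -1.005 over 4 measured of 9 listed genes, below random lists (-0.38 to 0.29). AT1G67600 had a ratio of -1.29 or lower, AT5G09570 had a ratio of -1.28 and SAL2 one of -0.73, while ChiC went the other way at 0.47. The median's spread over resampled members was 0.50. With 4 genes that do not all go one way, the list is too small to decide, and this explanation stays open. The first phosphate list, fixed before the data were examined, had 0 measured members. The same 4 genes had a median of 1.33 on Col-0 over NO, which shares the Col-0 array, so a high Col-0 array would give both values.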
